A study of Homo sapiens with 4 samples.

How the data were processed

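Gene expression was measured with 1-colour Affymetrix arrays in MIA PaCa-2, an established human pancreatic carcinoma cell line. Per the labels' protocols, the cells were transduced with a lentivirus carrying FLAG-tagged full-length ING3 or with a GFP lentivirus as control, and stable cells were selected. Total RNA was isolated from subconfluent cells with TRIzol and a column kit and labelled with biotin by the Ambion MessageAmp Premier protocol. There were 4 arrays, 2 for the control cells (arrays a and b) and 2 for the ING3 cells (arrays a and b), and the groups were taken from the titles. The series' design text calls the arrays of a group technical duplicates. The gene test's p-values below therefore set differences against the spread between technical duplicates of the 1 cell population per group that the labels distinguish. Camera, the list test below, instead sets the genes of a list against the other tested genes, with a preset correlation between genes. All p-values compare these 2 populations rather than the condition across independent cultures.

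The deposited table held linear signal intensity values for 54675 probe sets, which the authors made with Affymetrix Expression Console and MAS5, per the submitters' processing notes; versions are not given in the sources used here. In the deposited values, the mean without the lowest and highest 2% of probe sets was 499.9 on each array, so the arrays had been scaled to a common level. MAS5 subtracts mismatch probe signals and scales each array by 1 factor, so dim probe sets vary widely and differences that depend on brightness remain. The table held no detection calls. Arrays have no read depth, and the number of arrays limits the precision. No value column was left unmapped.

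Of the probe sets, 62 were control probe sets and were left out of the tests. GEO's platform annotation of 2016 listed 42898 probe sets, of which 41097 had 1 gene symbol and 1801 had several; 11777 probe sets were unnamed here. The symbols were looked up by gene ID in a RefSeq gene table of GRCh38.p14, which changed 0 symbols, since the table as given already held current ones (CCN1, for example), and 42 genes without an entry kept the annotation's symbol. Each gene was represented by its probe set with the highest mean log2 signal, which gave 19777 genes. Signals were transformed as log2(signal + 1). Fold changes are on that scale, which understates changes of dim genes. The 12190 genes whose mean log2 over all 4 arrays reached the median of all probe sets (a signal of about 64.6) were tested.

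Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, with no further normalization and no covariates). A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and a count with a size limit of 2-fold was given beside it. Each fit had 2 residual degrees of freedom per gene and borrowed 7.35 from the other genes. "Rose" and "fell" are used for called genes. Values are given as mean ± SD of the linear signal with n = 2 arrays, and log2 differences as ING3 minus control with the moderated standard error (SE).

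Before the data were examined, 43 gene lists were fixed (pathways, cell type and identity markers, complexes and reference genes). Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 40 lists tested. Camera with an estimated correlation and fry were run as alternatives. Each list's median log2 difference was also placed among 10000 random lists of the same size matched on mean signal. The lists of pancreatic acinar markers, endocrine and neuroendocrine markers and cancer-testis antigens had 0, 4 and 1 tested members and were not tested as lists.

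The genes named were chosen by a rule written before the data were examined: the ING family, the members of the NuA4/TIP60 complex, up to 4 called members of each list, and the 12 called genes with the largest difference in each direction whose groups did not overlap, whose brighter group reached the median signal of the tested genes, and whose probe set was not of the _x_at kind, which can cross-hybridise. Other genes that are named (CCN2, DUSP1, IER3, MYC, NR4A1, NQO1, GCLM, TXNRD1, AKR1C3, GSR, SLC7A11, FTL, ME1, HK2, PKM, PFKP, ENO1, LDHA, PGK1, GAPDH, PGAM1, ENO2, CIITA, CD74 and the HLA class II genes other than HLA-DPA1) were chosen after their values were seen. Genes with an adjusted p of 0.05 or more are given with their values only.

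On simulated data (12190 genes, 100 changed by each size), the gene test recovered 33% of genes changed by 1.5-fold and 70% of genes changed by 2-fold. There were 7 false calls among 110. The simulated genes had the real means, and variances drawn from the fitted intensity trend. The test assumes that same trend, so these rates hold only where it is right. Camera with the preset correlation recovered 10 of 10 lists of 25 genes shifted by 0.3 (log2) and called 0 of 30 unshifted lists. With an estimated correlation it recovered 0 of the 10, so a list that fails this alternative may still be shifted. The genes were simulated independently of each other, so this cannot show how camera does on lists whose members vary together. The alternatives tried were other constants added before log2 (0, 16 and 64), quantile, median and cyclic loess normalization, other filters, other variance models, the mean of a gene's probe sets, every probe set on its own, the duplicate letter as a block, a test against a 1.5-fold change, an untested 2-fold difference, and leaving out each array. Leaving out _x_at probe sets was added after seeing the data.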

Results

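The data comprised 4 arrays of MIA PaCa-2 pancreatic carcinoma cells, 2 from cells that expressed FLAG-ING3 from a lentivirus and 2 from cells that expressed GFP. ING3 is a subunit of the NuA4/TIP60 histone acetyltransferase complex, and the comparison asked which transcripts differ when it is overexpressed. The duplicates of a group were technical. Across the 12190 tested genes the duplicates correlated at r = 0.989 for the control cells and r = 0.991 for the ING3 cells, and the 4 correlations between the groups lay between 0.987 and 0.988; these are correlations across genes, which are not independent replicates. The SD of the log2 difference was 0.31 between the control arrays, 0.29 between the ING3 arrays and 0.32 to 0.35 between arrays of different groups. The number of genes 2-fold apart was 208 between the control arrays, 128 between the ING3 arrays, 228 and 252 between control array a and the ING3 arrays, and 177 and 170 between control array b and the ING3 arrays, so by this measure the control duplicates differed more than control array b did from either ING3 array. The ratio of 3' to 5' signal of the ACTB control probe sets, a measure of RNA quality, was 2.58 and 1.80 on the control arrays and 2.05 and 2.03 on the ING3 arrays. No pair of arrays held the same values throughout.

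The ING3 transcript was higher in the ING3 cells by 1.49-fold but did not pass the test over all genes. Its brightest probe set had a signal of 356 ± 24.9 (SD, n = 2) in control cells and 531 ± 14.5 (SD, n = 2) in ING3 cells, a log2 difference of 0.58 (SE 0.13, adjusted p = 0.071 by limma), with both ING3 arrays above both control arrays. The groups did not overlap for 49.2% of all tested genes, against 33.3% by chance with 2 arrays in each group. Adjusted over the list alone (the ING family, 5 genes), the limma p of ING3 was 0.0086. The other ING3 probe sets differed from the brightest. The second brightest had 274 ± 18.5 in control and 241 ± 27.1 in ING3 cells (SD, n = 2), and the third had 170 ± 22.9 and 171 ± 12.7. The dimmest, under the filter on dim genes, had 26.1 ± 1.36 and 40.7 ± 23.8, with 1 ING3 array below both control arrays. A probe set outside the sequence carried by the lentivirus would not detect the transgene; neither the positions of the probes nor whether the full-length insert holds untranslated regions was given in the sources used here. Among the other family members, the log2 difference was 0.22 for ING2 (SE 0.12), 0.15 for ING4 (SE 0.17), -0.17 for ING5 (SE 0.13) and -0.0024 for ING1 (SE 0.11), and none of the 4 passed the test.

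**Figure D1:**
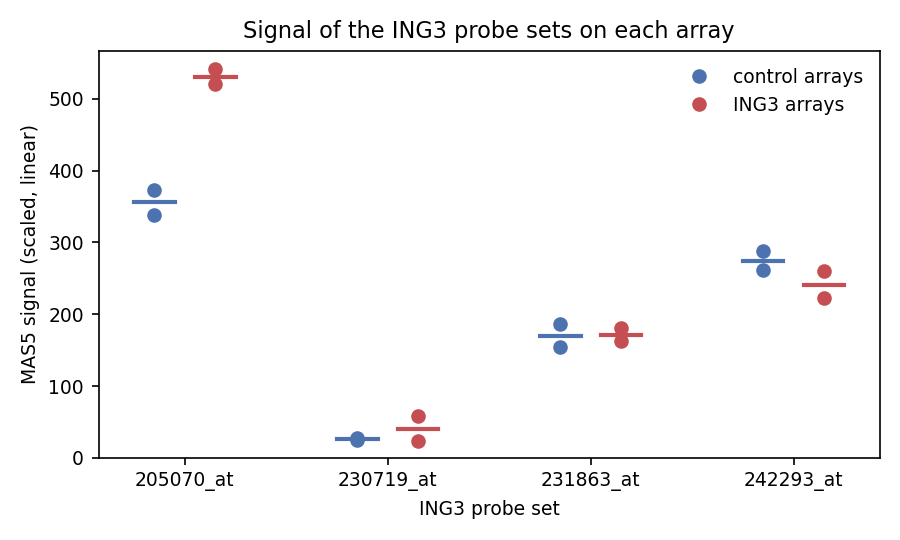
MAS5 signal (linear scale, y axis) of the 4 ING3 probe sets (x axis); each point is 1 array and each bar the mean of the 2 arrays of a group. Both ING3 arrays lie above both control arrays for the brightest probe set (means of 531 against 356), and the groups overlap or run the other way for the other probe sets.

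In the ING3 cells 125 genes rose and 58 fell. The changes were small: the median absolute log2 difference of the 183 called genes was 0.51, and 9 genes rose and 3 fell by 2-fold or more. MMP1, the interstitial collagenase, rose 2.80-fold from a signal of 160 ± 7.37 to 451 ± 20.9 (SD, n = 2; log2 difference 1.49, SE 0.17, adjusted p = 0.0058). AKR1C1, an aldo-keto reductase of steroid metabolism, rose 2.60-fold, from 748 ± 44.4 to 1948 ± 7.39 (log2 difference 1.38, SE 0.087, adjusted p = 0.00028). Its relative AKR1C2 rose 1.91-fold. Both were measured by probe sets of the cross-hybridising kind, so the share of each of these near-identical genes is uncertain. UCA1, a long noncoding RNA first described in bladder cancer, rose 2.06-fold from 3767 ± 258 to 7736 ± 62.7 (log2 difference 1.04, SE 0.066, adjusted p = 0.00028).

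Among the other genes that rose, APOBEC3G, a cytidine deaminase that restricts retroviruses, rose 2.28-fold from 354 ± 29.7 to 808 ± 8.06 (SD, n = 2). GLDC, the glycine decarboxylase of mitochondria, rose 2.25-fold, HLA-DPA1, an HLA class II chain, rose 2.10-fold, and SERPINE2, a secreted protease inhibitor, rose 2.03-fold. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose 1.96-fold and SLC2A3, a glucose transporter, rose 1.70-fold. ERCC6, a DNA repair ATPase, rose 1.92-fold and the noncoding RNA LINC00525 rose 1.73-fold. TGM2, a transglutaminase that crosslinks matrix proteins, rose 1.71-fold and CCN1, a matricellular protein, rose 1.68-fold. KLF2, a zinc finger transcription factor, rose 1.70-fold.

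Among the 58 genes that fell, MLLT11 fell by 0.91 on the log2 scale, from a signal of 1150 ± 6.01 to 614 ± 32.2 (SD, n = 2; SE 0.098, adjusted p = 0.0050). TP53I3, a p53-inducible quinone oxidoreductase, fell by 0.60 on the log2 scale, from 3027 ± 26.5 to 2002 ± 76.4 (SE 0.069, adjusted p = 0.0064). ABCA8, a lipid transporter, was 1.54-fold lower, from 2963 ± 18.1 to 1923 ± 43.3. The signalling genes SHC3, an adaptor protein, and PIK3R3, a regulatory subunit of PI3-kinase, were 1.63-fold and 1.62-fold lower, and CREB3, a transcription factor of the endoplasmic reticulum, was 1.63-fold lower. The zinc finger genes ZNF512 and ZNF512B were 1.57-fold and 1.55-fold lower. ABHD3, a phospholipase, was 1.55-fold lower and TM7SF2, a sterol reductase of cholesterol synthesis, 1.53-fold lower. The antisense transcripts HLA-F-AS1 and PRRT3-AS1 were 1.74-fold and 1.51-fold lower.

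The counts depended on the variance model and on the control arrays. With eBayes without an intensity trend limma called 0 genes (1686 genes at an unadjusted p under 0.05, against 2161 with the trend), and without control array a or without control array b it called 2 genes, AKR1C1 and UCA1 in each case. Against a 1.5-fold change only AKR1C1 passed. Of the 97 called genes with another probe set past the filter, 67 had all their other probe sets going the same way. Among the named genes that were called, ABCC5, ASAP1, CFLAR, DUSP1 and ITGB4 had at least 1 that went the other way.

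**Figure D2:**
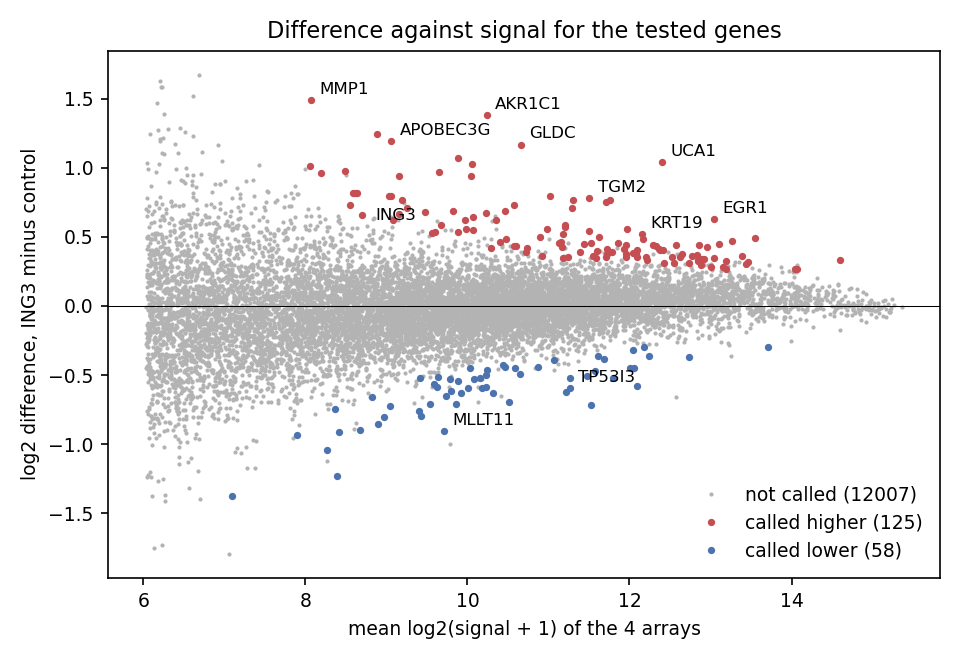
Log2 difference of ING3 minus control (y axis) against mean log2(signal + 1) over the 4 arrays (x axis) for the 12190 tested genes; red points are the 125 genes that rose, blue points the 58 that fell, and grey points the genes not called. The spread of the grey points narrows from dim to bright genes, and the called genes lie at its edges.

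**Figure D3:**
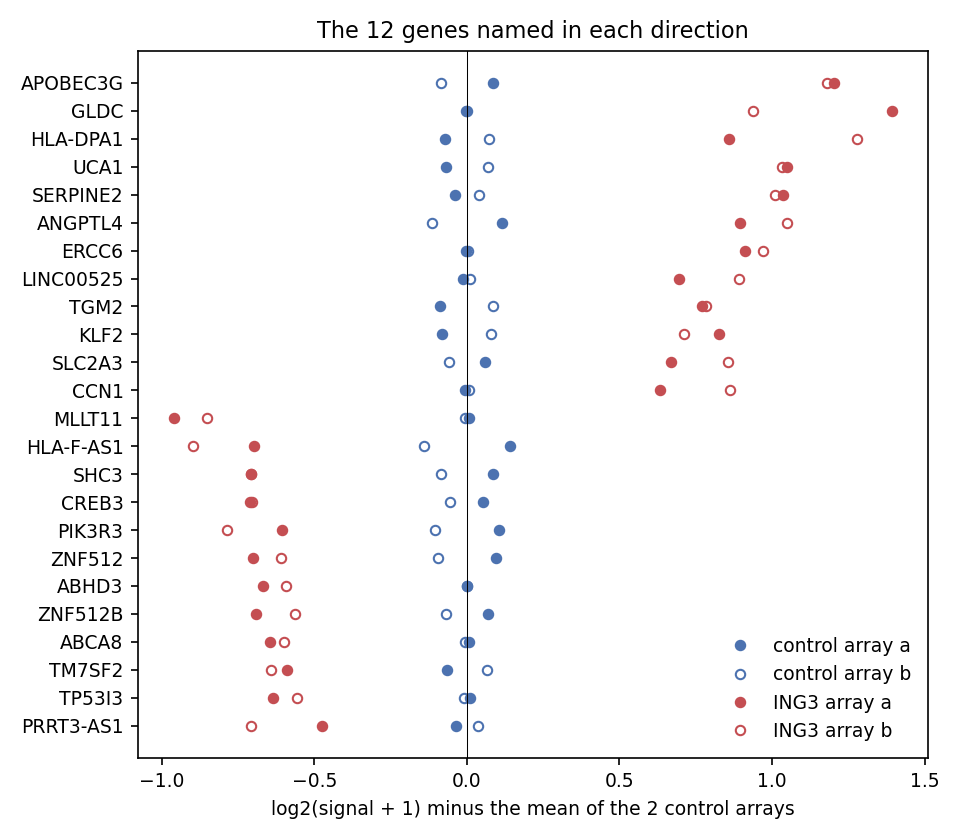
Log2(signal + 1) of each array minus the mean of the control arrays (x axis) for the 12 named genes in each direction (y axis); filled and open points are arrays a and b. For each gene both ING3 arrays lie on one side of both control arrays, as the rule for naming requires.

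Of 23 measured members of the list of immediate early and AP-1 genes, the fast transcriptional targets of growth factor signalling, 6 rose, 0 fell and 17 did not pass (18 rose adjusted over the list alone), and 22 had a higher mean in the ING3 cells. The median log2 difference was 0.30, above all 10000 matched random lists, and camera gave an adjusted p of 1.2e-14 (adjusted p = 0.38 with an estimated correlation). NR4A1, the member with a lower mean, had a log2 difference of -0.48 (SE 0.54). FOSL1, an AP-1 subunit, rose 1.66-fold, JUNB, another, rose 1.63-fold, and EGR1, a zinc finger factor induced by ERK signalling, rose 1.54-fold from 6825 ± 554 to 10535 ± 842 (SD, n = 2). KLF2 and CCN1, given above, belong to the list, and DUSP1, a MAP kinase phosphatase, rose 1.28-fold on its brightest probe set, while its other probe set past the filter had a log2 difference of -0.28.

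The list of ERK pathway output genes had 3 of 19 members that rose and 0 that fell (10 rose adjusted over the list alone), with a median log2 difference of 0.20 and a camera adjusted p of 1.8e-07 (adjusted p = 0.38 with an estimated correlation). Its members that rose were FOSL1, EGR1 and DUSP5, an ERK phosphatase, at 1.54-fold. It shares EGR1, FOSL1, IER3 and MYC with the list of immediate early genes, and without these 4 genes camera gave an unadjusted p of 3.1e-05 (unadjusted p = 0.047 with an estimated correlation, against 0.033 for the whole list, whose adjusted p is the 0.38 above). IER3 and MYC had log2 differences of 0.31 (SE 0.088) and 0.29 (SE 0.071) and did not pass. Among YAP/TAZ targets, 3 of 19 rose and 0 fell: CCN1, ASAP1 at 1.35-fold and the receptor tyrosine kinase AXL at 1.35-fold (9 rose and 1 fell adjusted over the list alone). Their median log2 difference was 0.20 and the camera adjusted p was 0.00029 (adjusted p = 0.45 with an estimated correlation). The size for AXL is uncertain: its other probe set past the filter had a log2 difference of 2.41, against 0.44 for the brightest. The YAP/TAZ list shares CCN1 and CCN2 with the list of immediate early genes. Without them its median was 0.19, and camera gave an unadjusted p of 0.0020 (unadjusted p = 0.14 with an estimated correlation). Among TGF-beta targets, 3 of 20 rose and 0 fell: ID2 at 1.47-fold, TGFBI at 1.37-fold and ID1 at 1.27-fold (6 rose adjusted over the list alone). Of the 20 members 11 had a higher and 9 a lower mean in the ING3 cells, with a median log2 difference of 0.11, and of 0.055 without CCN2, which the list of immediate early genes also holds and which did not pass (log2 difference 1.02, SE 0.21). Camera gave an adjusted p of 0.0077 (adjusted p = 0.38 with an estimated correlation).

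Of 22 NRF2 targets, which serve detoxification and redox balance, 3 rose and 0 fell (9 rose adjusted over the list alone), with a median log2 difference of 0.18 and a camera adjusted p of 1.1e-05 (adjusted p = 0.38 with an estimated correlation). AKR1C1, AKR1C2 and HMOX1, the inducible heme oxygenase (1.59-fold), were the members that rose. AKR1C1 and AKR1C2, read by probe sets of the cross-hybridising kind, may not be separate signals in this count or in camera. Of the 22 members 17 had a higher and 5 a lower mean in the ING3 cells. Among those that did not pass, the log2 differences of NQO1, GCLM and TXNRD1 were 0.16, 0.21 and 0.30, and those of AKR1C3, GSR, SLC7A11, FTL and ME1 were -0.29, -0.14, -0.13, -0.080 and -0.076. Of 32 genes of hypoxia and glycolysis, ANGPTL4 and SLC2A3 rose and 28 had a higher mean in the ING3 cells (8 rose adjusted over the list alone, camera adjusted p = 3.7e-05, and adjusted p = 0.38 with an estimated correlation). The glycolytic enzymes varied. HK2, PKM, PFKP and ENO1 differed by 0.42, 0.24, 0.23 and 0.14 (log2). LDHA, PGK1, GAPDH, PGAM1 and ENO2 differed by 0.0065, 0.048, -0.033, -0.036 and -0.18. None of these enzymes passed the test over all genes. Of 44 genes of the unfolded protein and integrated stress response, TRIB3, a pseudokinase induced through ATF4, rose 1.39-fold and 0 fell (11 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.00024, and adjusted p = 0.38 with an estimated correlation).

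Of 19 epithelial genes 3 rose and 0 fell (7 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.00048, and adjusted p = 0.38 with an estimated correlation): the keratins KRT19, at 1.43-fold from 3816 ± 159 to 5470 ± 135 (SD, n = 2), and KRT8, at 1.25-fold on a probe set of the cross-hybridising kind, and the mucin MUC1, at 1.33-fold. Of 21 mesenchymal genes PLAUR, the urokinase receptor, rose 1.42-fold and PLAU, urokinase itself, rose 1.25-fold (3 rose and 1 fell adjusted over the list alone), and the list did not pass (camera adjusted p = 0.96). Of 32 genes of the G2/M phase only ANLN, a cytokinesis protein, rose (1.24-fold; 2 rose adjusted over the list alone), 24 had a higher mean in the ING3 cells, and camera gave an adjusted p of 0.00022 (adjusted p = 0.38 with an estimated correlation). Of 9 replication-dependent histone genes H2BC21 rose 1.77-fold (5 rose adjusted over the list alone; camera adjusted p = 0.0029, and adjusted p = 0.38 with an estimated correlation). Of 40 genes of oxidative phosphorylation 0 rose and ATP5MC1, a subunit of ATP synthase, was 1.41-fold lower (3 rose and 2 fell adjusted over the list alone). That list passed upward in camera (adjusted p = 0.013, and adjusted p = 0.45 with an estimated correlation), but its median of 0.061 stood at the 75.9th percentile of random lists of the same brightness, and it did not pass after quantile normalization (adjusted p = 0.98) or cyclic loess (adjusted p = 0.83).

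**Figure D4:**
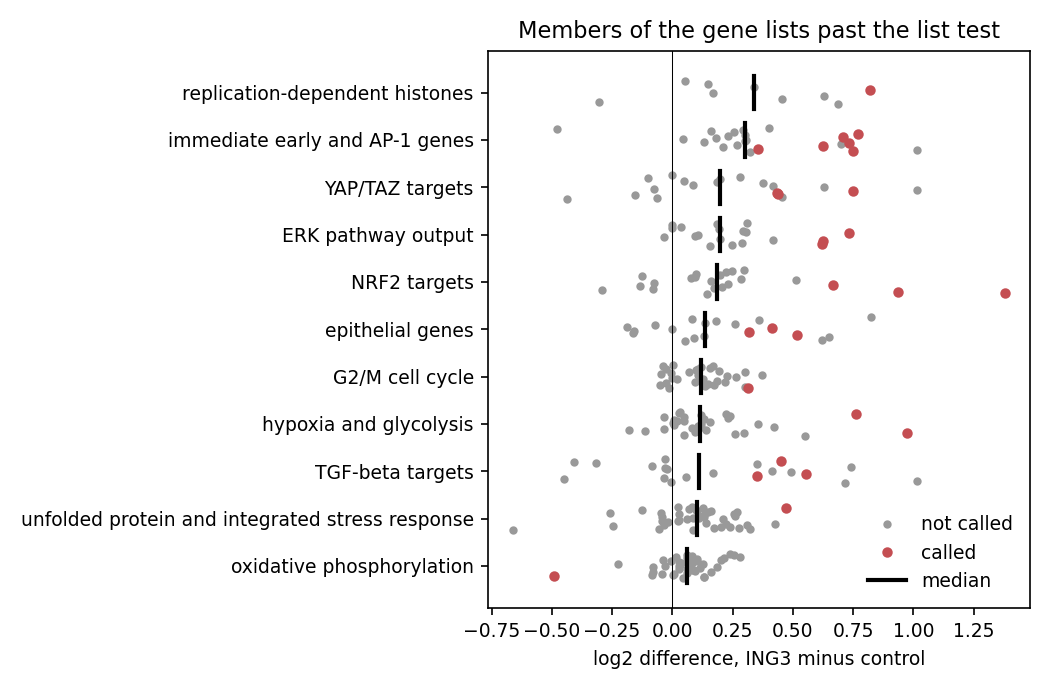
Log2 difference of ING3 minus control (x axis) for each tested member of the 11 gene lists that passed camera with the preset correlation (y axis); red points are called genes, grey points genes not called, and black bars medians. All medians lie above 0, from 0.061 for oxidative phosphorylation to 0.34 for histones, and few members of any list were called.

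The remaining lists did not pass. In the NuA4/TIP60 complex 0 of 19 members were called over all genes, and ING3 alone passed adjusted over the list alone (camera adjusted p = 0.54). The log2 differences of the catalytic subunit KAT5, of the scaffold TRRAP and of the ATPases EP400, RUVBL1 and RUVBL2 were -0.081, -0.016, -0.28, -0.14 and 0.13, with SE of 0.13, 0.085, 0.11, 0.084 and 0.063. No member was called among 31 histone acetyltransferase and deacetylase genes (camera adjusted p = 0.88). Of 22 p53 targets GDF15, a stress cytokine measured by a probe set of the cross-hybridising kind, rose 1.70-fold and TP53I3 fell, with 20 not called (2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.96). Of 33 apoptosis regulators CFLAR, a caspase-8 inhibitor, was called at 1.22-fold higher on its brightest probe set, but 3 of its 11 other probe sets past the filter went the same way (3 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.52). Of 39 interferon-stimulated genes HERC5, a ubiquitin-like ligase, rose 1.76-fold and IFITM1 rose 1.20-fold (3 rose adjusted over the list alone; camera adjusted p = 0.056). The ING family as a list had a camera adjusted p of 0.34.

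Other lists that did not pass held at most 2 called members. In the basal-like pancreatic cancer list UCA1 and LEMD1 (1.95-fold) rose among 10 genes, and 0 of 7 genes of the classical list were called (camera adjusted p = 0.19 and 0.58). ITGB4, an integrin of hemidesmosomes, rose 1.60-fold among 14 adhesion genes (0.40), DKK1, a secreted WNT antagonist, rose 1.28-fold among 7 WNT targets (0.23), and NRARP rose 1.34-fold among 15 Notch pathway genes (0.079), with the camera adjusted p in parentheses. Of 17 genes of drug transport and metabolism ALDH1A1, a retinaldehyde dehydrogenase, rose 1.25-fold and ABCC5, an efflux pump, was 1.44-fold lower (0.74). MMP1 was the member that rose among 13 matrix metalloproteinase genes (0.079), GDF15 among 15 senescence genes (0.11) and HMOX1 among 16 heat shock genes (0.26), and TM7SF2 was the member that fell among 17 cholesterol synthesis genes (0.81). KRT19 and MUC1 rose among 8 pancreatic duct markers (0.16). Adjusted over the list alone, 3 genes rose in each of the basal-like, duct and heat shock lists, 2 in the WNT and senescence lists and 1 in the Notch and metalloproteinase lists, 2 rose and 2 fell among adhesion genes, 2 rose and 1 fell among cholesterol genes, and 1 rose and 1 fell among drug transport genes.

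No member was called in the lists of DNA replication and S phase (35 genes, 0.88), DNA damage repair (31, 0.96), NF-kB and inflammatory cytokines (22, 0.88), fatty acid synthesis (18, 0.20), cytosolic ribosomal proteins (43, 0.54), ribosome biogenesis and MYC targets (34, 0.80), autophagy and lysosome (34, 0.88), axon guidance (24, 0.96) and housekeeping genes (22, 0.49), given with the number of tested genes and the camera adjusted p. Adjusted over the list alone, 2 genes rose and 4 fell in the DNA replication list, 1 fell in the NF-kB list, and 1 rose in each of the axon guidance and housekeeping lists. No member was called over all genes for the markers of other cell types, with 9 tested genes for fibroblasts and stellate cells (0.44, with 1 that fell adjusted over the list alone) and 6 for leukocytes and endothelium (0.58). The median log2 difference was negative while camera ranked the list upward for the basal-like, duct, DNA repair and chromatin lists, and positive while camera ranked it downward for the NF-kB list. For the p53 list the median was negative and the mean positive, and for ribosome biogenesis the median was positive and the mean negative. Camera's adjusted p with an estimated correlation was 0.45 or more for each of the lists that did not pass with the preset one.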

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

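The probe sets with no single gene symbol were left out of the comparisons above, and were tested after those results were seen. Of the 4748 such probe sets past the filter on dim genes, 3 were higher in the ING3 cells than in the control cells and 1 was lower by the same limma test. The log2 differences of the higher ones were 0.95 (SE 0.075, adjusted p = 0.0073) and 0.81 (SE 0.079, adjusted p = 0.017) for a pair of probe sets listed with several genes, and 0.70 (SE 0.076, adjusted p = 0.022) for one without a listed gene. The lower one, also without a listed gene, differed by -0.93 (SE 0.10, adjusted p = 0.022). Both ING3 arrays lay on one side of both control arrays for all 4, as they did for 49.2% of the tested genes.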

How the results depend on the processing

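The counts of called genes depended on the setting. Beside 125 genes higher in ING3 cells, 58 genes lower in ING3 cells, 9 genes at least 2-fold higher in ING3 cells and 3 genes at least 2-fold lower in ING3 cells, quantile normalization gave 79, 36, 14 and 0, cyclic loess gave 36 that fell and 14 and 0 at 2-fold or more, and no filter gave 42 that rose, 12 that fell and 0 at least 2-fold lower. EBayes without an intensity trend gave 0 in each of the 4 counts, with a smallest adjusted p of 0.24. A test against a 1.5-fold change gave 1 that rose, 0 that fell, and 1 and 0 at 2-fold or more. The mean of a gene's probe sets gave 26 and 11, and every probe set on its own gave 67 and 28. The 75th percentile filter gave 0 genes at least 2-fold lower, and adding 64 before log2 or leaving out _x_at probe sets (chosen after seeing the data) gave 1. A 2-fold difference of the means with no test gave 36 and 33 genes. The cause was not tested for any of these. Leaving out 1 array gave 2 to 157 genes that rose, 0 to 86 that fell, 1 to 9 at least 2-fold higher and 0 to 12 at least 2-fold lower, with the lowest values where control array a or b was left out; the lone array of the group is then assumed to vary like the others. All 183 called genes were among the 442 called with the duplicate letter as a replicate block (263 rose, 179 fell, 12 at least 2-fold lower, and the ING3 transcript at 0.58 with an adjusted p of 0.040), but the letters share only a label: arrays of one letter deviated together at r = 0.029 across genes. ING3 stayed positive in every setting, from 0.23 with the mean of its probe sets to 0.66, and passed only with the block; its adjusted p otherwise ran from 0.053 with the 75th percentile filter to 0.66 with the mean of probe sets, and was 1 against a 1.5-fold change. The list count of 11 became 0 with camera's estimated correlation and 2 with fry (the histone and the unfolded protein and integrated stress response lists). It lay between 9 and 15 in the other settings. The estimated correlation also recovered 0 of 10 lists that were shifted in simulated data. Its failure to pass a list here therefore cannot decide whether that list was shifted. Genes were independent in that simulation, so it cannot show whether the preset correlation is right for lists whose members vary together. Among the 56 called genes named by the rule, only CFLAR reversed. Its log2 difference was -0.18 with the mean of its probe sets and -0.19 without _x_at probe sets. The direction of the other called genes was not followed across settings. Among the lists, camera's direction reversed only for oxidative phosphorylation, after quantile normalization (median 0.00043) and cyclic loess (median 0.0024). For the 56 named genes that were called, set against each other setting in turn, the call was kept in 742 of 1110 comparisons, lost in the same direction in 366 and reversed in the 2 of CFLAR. Genes under a signal of about 64.6 were not tested, and in simulated data 2-fold changes were recovered in 70% of genes over all signals.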

Other observations

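The tests in this part were chosen after the results were seen, except the test of chromosome copy number. HLA class II genes, whose products present antigen, were on none of the fixed lists. HLA-DRB1 rose from a signal of 307 ± 15.7 to 730 ± 13.6 (SD, n = 2; log2 difference 1.25, SE 0.13, adjusted p = 0.0044) on a probe set that can cross-hybridise with its relatives, and HLA-DPA1 rose from 655 ± 46.7 to 1387 ± 282. HLA-DRA had 112 ± 14.5 and 210 ± 26.6, HLA-DMA had 186 ± 37.4 and 259 ± 26.1, and HLA-DPB1 had 74.3 ± 0.823 and 119 ± 13.2 in control and ING3 cells, and none of these 3 passed the test. A hypothesis is that the genes of this pathway may have risen together. Without the 2 genes that prompted it, 7 of 8 tested genes of the class II pathway, CD74 and CIITA among the 8, had a higher mean in the ING3 cells. The median log2 difference of the 8 was 0.47. Camera gave an unadjusted p of 0.0096 for these 8 genes, and 0.20 with an estimated correlation. The gene for the class II transactivator, CIITA, had 78.7 ± 11.5 and 61.2 ± 14.96, close to the filter on dim genes. Among the genes with a higher mean, HLA-DPB1 and HLA-DOA (67.4 ± 14.9 in control cells) were also close to it. The groups overlapped for CIITA, HLA-DOA and CD74, and HLA-DOA and HLA-DQB1 were measured by probe sets of the cross-hybridising kind.

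The first pattern weighed was the set of 183 called genes. By these ratios RNA quality did not part the groups: the ACTB 3' to 5' ratios of 2 of the 2 ING3 arrays lay within the range of the control arrays, and for GAPDH 1 did, with 0.903 on the other against 0.905 and 0.934 on the control arrays. The control arrays themselves lay far apart for ACTB, at 2.58 and 1.80, so this cannot exclude a part played by RNA quality. A difference in chromosome copy number between the 2 cell populations is not borne out as the whole cause: the uncalled neighbours of called genes (10 on each side, by position in GRCh38.p14) moved the same way by a mean of 0.012 (log2; 95% bootstrap interval 0.0037 to 0.020), under the bound of 0.1 set before the test, although the neighbours of 14 called genes reached that bound, so it stays open for these. The real split of the 4 arrays called 183 genes and limma called 0 in either of the others (260 and 228 genes at an unadjusted p under 0.05), but the 3 splits, of which 1 called as many, are too few for a share under 0.05. Differences between the 2 selected populations other than ING3 itself remain open, since the labels distinguish 1 population per group.

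The second pattern was the disagreement among the ING3 probe sets. The second brightest had a log2 difference of -0.19 (SE 0.18) and the third of 0.018 (SE 0.23), against 0.58 for the brightest. Whether every probed part of the endogenous transcript was higher stays open, since these values are the disagreement itself and no separate measurement bears on it. Expression from the lentivirus of a sequence that some of the probe sets miss also stays open and untested, because the positions of the probes were not given.

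The third pattern was the upward shift of immediate early and AP-1 genes. Control array a alone does not account for it, since the median log2 difference was 0.28 without that array, against 0.30 with it. The scaling of the arrays does not account for it either, since the lower of the medians after quantile normalization and cyclic loess was 0.31. The state of the culture at harvest, such as density or time since feeding, could give the same shift, because these genes respond to serum within minutes to hours; with 1 culture per group distinguished by the labels, this and an effect of ING3 cannot be told apart.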
